A study of Mus musculus with 2 samples.

How the data were processed

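Total RNA of 2 samples of sorted mouse embryonic fibroblasts was measured on 1 short oligonucleotide array each, with probe set names of the Affymetrix kind. The deposited values are intensities, 1 per probe set on a linear scale with 1 decimal, as the values themselves show. The software, the background step, the detection calls and any scaling behind them are not given in the sources used here. The mean signal after trimming 2% of the probes at each end was 150.05 on both arrays, as a global scaling to a target would leave it. Groups were taken from the sample titles, which name a Cre-infected and a vector-infected sample, so that Cre and Vec hold 1 sample each.

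Of 22690 probes, 64 are controls and were kept out of the gene analysis. Of the other 22626, 20380 carry 1 gene symbol in the platform annotation used here, 691 carry several and 1555 none. Probes with several symbols or none were not named. Symbols of 20351 probes were updated through their gene identifiers with a RefSeq gene table of assembly GRCm38.p6, used for names only, and no genome coordinates are printed because the files name no build. This gave 12393 genes. For 2 of the genes fixed by name no probe with a single symbol was used here, and they were not analysed here.

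The Cre array was scaled so that the median ratio of the probes past the filter was 1, and the factor came out as 1, so that the values equal those deposited. Signals under the floor of 9.5, the 20th percentile of all values, were set to it before log2, and a fold against a floored value is written as at least that fold. A probe passed the filter when its mean signal over the 2 arrays was at or above the median over probes, 53.2, which 11315 probes and 6842 genes did. A gene was represented by its brightest probe. Genes at least 2-fold apart were counted, with no test, because there is 1 sample per group. The SD between probes of the same gene was used as a technical scale only. For each gene list with at least 5 genes past the filter, the median log2 ratio of Cre over Vec was placed among 10000 random lists of the same size, drawn from the same 10 bins of mean signal with a fixed seed, and a list outside the central 95% was said to stand apart.

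The samples, the 43 gene lists, the settings above, the alternatives not named as added and the rule for named genes were fixed before the data were examined. By that rule the text names the target gene and Itga4; the 12 genes with the largest rise and the 12 with the largest fall past the filter, at least 2-fold, not at the floor on the brighter side, and with every other probe past the filter in the same direction; up to 4 members of each list with the largest log2 ratios by size; and Trp53, Jun, Cdkn1a, Mdm2, Bax, Ppp2ca, Ppp2r1a, Ppp4c, Ppp6c and Mid1 where measured. A gene outside the rule is said to have been named after its value was seen.

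The alternatives fixed beforehand were values as deposited, quantile normalization, lowess centring with a span of 0.3, a floor at the 40th percentile, a pseudocount of 9.5 in place of the floor, the median over a gene's probes, leaving out probe sets that may cross-hybridize, no filter or a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. Added after the data were seen were scaling on the spike-in probes, counting only genes with at least 2 probes that were all at least 1.5-fold in the same direction, lists without members shared with another list, and the next brightest probe of each gene.

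The steps were tested on simulated data for the comparison of Cre with Vec, with the real mean signals and noise as large, at each signal, as the spread between the 2 real arrays. Of genes changed by 1.5-fold, 14% of 50 were called 2-fold, of those changed by 2-fold 56% of 50, and of those changed by 3-fold and 4-fold 100% of 49 each, among 6828 genes tested. Of 6609 unchanged genes, 24 were called, or 0.36%. A planted list shift of 0.4 was recovered as 0.407, with 4 of 32 unshifted lists outside their range. Over 20 simulated pairs without any change, 39 of 661 lists, or 5.9%, lay outside. The number of arrays limits the precision of every value. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.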

Results

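Mouse embryonic fibroblasts (MEFs, cells grown from embryos) carrying a floxed alpha4 allele were compared after infection with a retrovirus. A floxed allele is flanked by loxP sites, so that the Cre recombinase can cut out the part between them. The MIGR1 retrovirus used here carries green fluorescent protein (GFP), and in 1 of the 2 samples it also carries Cre. GFP-positive cells were collected by flow sorting at 24 hours, and total RNA was taken at 48 hours. The group called Cre here received the Cre virus, and the group called Vec received the virus without Cre. Each group holds 1 sample on 1 array, so no difference has a replicate check, no p-value is given, and the number of arrays limits the precision of every value. The 22690 probe signals ranged from 0.1 to 8053.7 on the Cre array and from 0.1 to 9372 on the Vec array, with medians of 52.8 and 54.1. Signals of the 2 arrays had a Spearman correlation of 0.973 across probes, which are not independent replicates.

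The first question was whether the floxed gene itself was lower in the Cre library. Alpha4 is the name used in the labels, and Igbp1, the gene of the PP2A-associated protein alpha4, was taken as its identity from knowledge of the study. The brightest of its 4 probes read 115.8 in Cre and 152.4 in Vec, 1.32-fold lower in Cre (log2 ratio -0.40). The next brightest read 98.6 and 98.8, and a dimmer probe, under the filter, read 49.5 and 44.4. The dimmest probe, also under the filter, read 2.9 in Cre, under the floor of 9.5, and 32.6 in Vec, which is at least 3.43-fold lower in Cre. The labels do not give the deleted part of the gene, and a probe outside it does not check the deletion. Itga4, the integrin subunit that shares the short name alpha4, was under the floor on both arrays with all 3 of its probes. The level of Igbp1 therefore rests on probes that differ from one another, and without the probes that may cross-hybridize its log2 ratio was -0.003.

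The second question was which transcripts differed between the Cre and Vec libraries. Of 6842 genes past the signal filter, 38 were at least 2-fold higher in Cre and 51 at least 2-fold lower, 89 in all or 1.3%. Trp53inp1 and Cdkn1a, both p53 target genes, were among the higher genes at 3.73-fold and 3.58-fold. Among the lower genes were the collagen gene Col3a1, at 3.50-fold, the neutrophil-attracting chemokine genes Cxcl5 and Cxcl1, at 3.44-fold and 3.37-fold, and Cplx2, at 3.39-fold. The median log2 ratio over genes was 0.04, and the log2 ratios of probes of the same gene differed with an SD of 0.28 over 2428 genes with at least 2 probes. The 2-fold rule lies above 2 such SDs, which come to 0.57, but this SD covers probe differences and not differences between cultures.

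**Figure D1:**
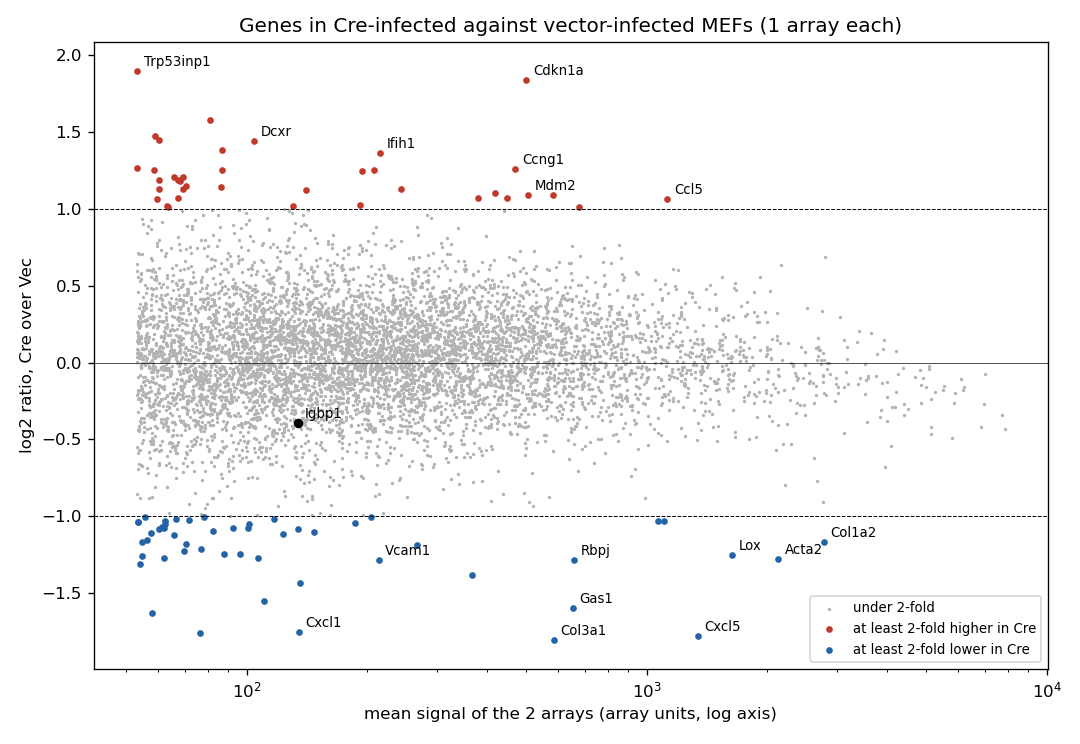
Each point is 1 of the 6842 genes past the filter, with the mean signal of the 2 arrays in array units on a log axis and the log2 ratio of Cre over Vec on the other axis. The 38 genes at least 2-fold higher are red, the 51 at least 2-fold lower are blue, and Igbp1, in black, lies at -0.40; the spread of the ratios is wider among dim genes.

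Of the 12 genes with the largest excess in Cre, 4 belong to the list of p53 targets, namely Trp53inp1, Cdkn1a, Dcxr and Ccng1. Cdkn1a, which encodes the cell cycle inhibitor p21, read 782.4 in Cre and 218.3 in Vec, and its other probe read 124.4 in Cre against a Vec value under the floor, at least 13.1-fold higher. Trp53inp1 read 83.9 and 22.5, its other probe, under the filter, read 36.7 and 32.5, and its log2 ratio of 1.90 became 1.34 with the floor at the 40th percentile and 1.55 with a pseudocount. Ccng1, which encodes cyclin G1, read 661.4 and 276.6, 2.39-fold higher, and its 3 probes had log2 ratios from 0.72 to 1.26. Dcxr, an enzyme of sugar reduction, was 2.72-fold higher, and Ifih1, a sensor of double-stranded RNA, was 2.58-fold higher at 310.9 against 120.7. Hspa1a, an inducible heat shock protein gene, was 2.39-fold higher, although its near-identical copy Hspa1b, looked up after this value was seen, read 557.1 and 571.3, so the fold of Hspa1a is uncertain. The others were C77080 (log2 ratio 1.58), Crtc2 (1.48), Plppr2 (1.45), Usp20 (1.38), Ubr3 (1.27) and Ypel5 (1.25). The other probes of Usp20 and Ypel5, under the filter, had log2 ratios of 0.10 and 0.12.

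Of the 12 genes with the largest deficit in Cre, Col3a1 and Col12a1 belong to the matrix list and Cxcl5, Cxcl1 and Vcam1 to the list of NF-kB targets. Col3a1 read 260.4 in Cre and 911.2 in Vec, and Col12a1 was 2.93-fold lower. Cxcl5 read 603.6 and 2077.1, and Cxcl1 read 61.7 and 208.2. Vcam1, a cell adhesion molecule induced by inflammation, was 2.44-fold lower, with log2 ratios from -1.92 to -1.28 over its 3 probes. Gas1, a growth arrest-specific gene, read 323.8 and 981.6, 3.03-fold lower. Rbpj, the DNA-binding partner of Notch, read 383.2 and 932.4, and its other probe had a log2 ratio of -1.73. The remaining log2 ratios were -1.76 for Cplx2, -1.63 for Steap4, -1.43 for Trps1, -1.38 for Utp3 and -1.31 for Myo1h.

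Dim genes made up much of both counts. Of the dimmest 685 genes, with mean signals of 53.2 to 70.45, 16 were higher and 18 lower. Of the 89 genes, 23 had at least 2 probes past the filter, and in 20 of these all the probes went in the same direction, against 53.9% of all genes with several probes. With the rule that every probe had to be at least 1.5-fold in the same direction, chosen after the data were seen, 5 genes were higher, namely Ccng1, Cdkn1a, Mdm2, Rsad2 and Vat1, and 8 were lower, namely Ccdc80, Col1a2, Gas1, Lox, Pdgfrb, Rbpj, Scd2 and Vcam1. Vat1 and Ccdc80 were named after their values were seen. With a pseudocount in place of the floor, Atf3, Bst2, Krt8, Map1lc3a and Met were among the genes that came under 2-fold, and 29 higher and 29 lower genes were left. Leaving out the filter gave 256 genes higher and 323 lower, and a filter at the 75th percentile of signal gave 14 and 14.

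The gene lists fixed before the data were examined asked which pathways shifted together. Of 43 lists, 33 had at least 5 genes past the filter. Of these, 4 lay above and 10 below the central 95% of 10000 random lists of the same size and signal. For genes drawn at random this range leaves 1.7 lists outside. Genes of a pathway can vary together between any 2 cultures, and some lists share members. More than 1.7 lists may therefore lie outside without any effect of Cre. The p53 targets, oxidative phosphorylation genes, proteasome subunits and Nrf2 antioxidant genes lay above. Chemokines and cytokines, matrix genes, NF-kB targets, actin and smooth muscle genes, fatty acid and cholesterol synthesis genes, fibroblast markers, hypoxia genes, growth factor genes and glycolysis genes lay below. These percentiles describe the 2 libraries and are not tests of the conditions. With the next brightest probe of each member, chosen after the data were seen, the lists of NF-kB targets, Nrf2 genes, glycolysis, cholesterol and fatty acid synthesis and growth factors, with 6 to 12 genes each, lay inside their random ranges.

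**Figure D2:**
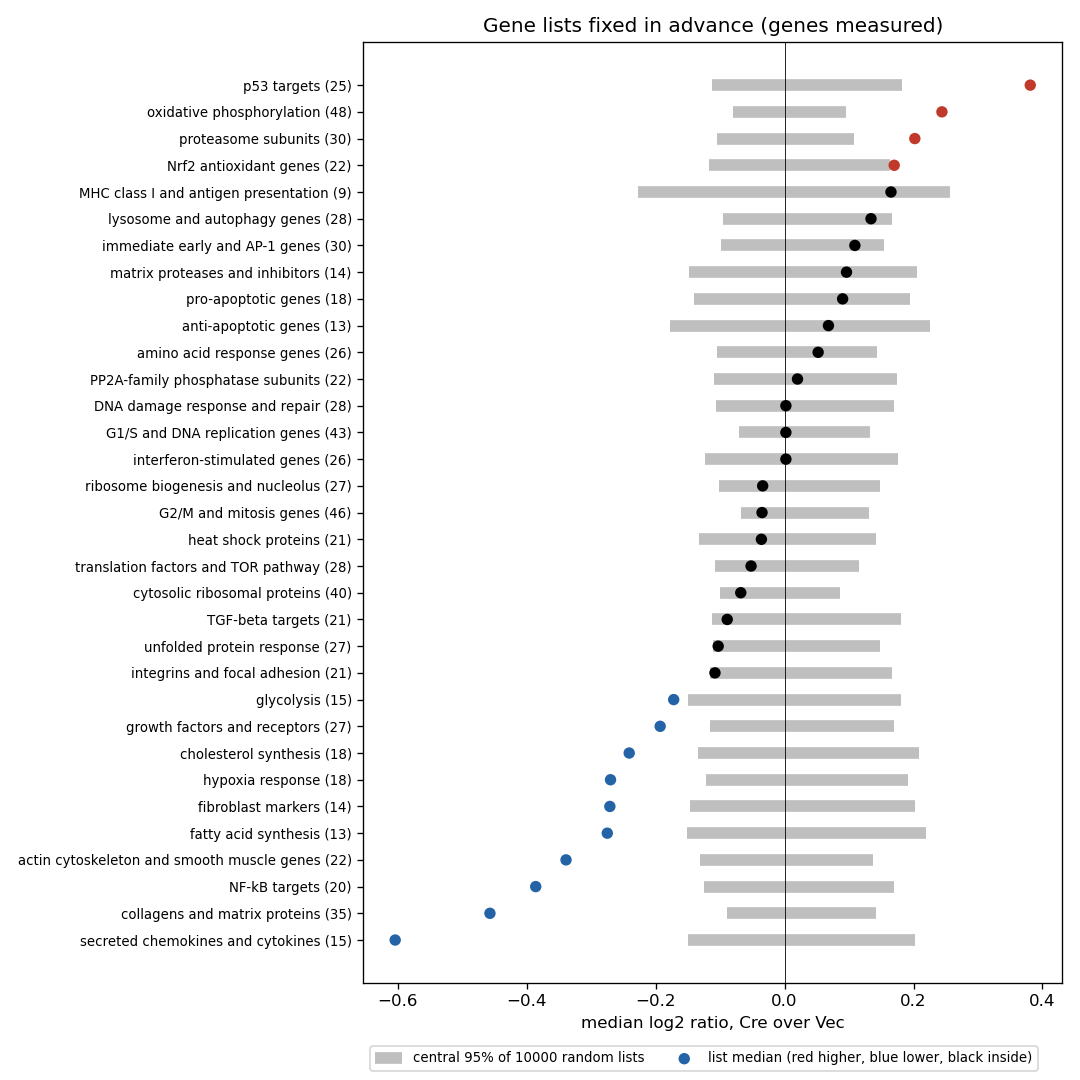
Each row is 1 of the 33 lists with its number of measured genes, and each dot is the median log2 ratio of Cre over Vec. Grey bars show the central 95% of 10000 random lists matched on signal; the p53 target list, at 0.38, lies farthest to the right, and the list of chemokines and cytokines, at -0.60, farthest to the left.

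The p53 targets had a median log2 ratio of 0.38 over 25 genes, above all 10000 random lists, whose central range was -0.11 to 0.18. In this list 5 genes were at least 2-fold higher, none was 2-fold lower, and 21 of the 25 ratios were positive. The 5 were Trp53inp1, Cdkn1a, Dcxr, Ccng1 and Mdm2. Mdm2, which encodes the ubiquitin ligase of p53, read 686.5 and 322.3, 2.13-fold higher. The pro-apoptotic list (0.09 over 18 genes, percentile 76.5) and the anti-apoptotic list (0.07 over 13 genes, percentile 64.8) lay inside their random ranges. No gene of either list past the filter was at 2-fold on its brightest probe. Among these genes, the BH3-only genes Bad and Hrk had log2 ratios of -0.53 and -0.52, and the survival genes Pim1 and Bcl2l1 0.58 and 0.51. The nuclease gene Endog had 0.51, and its other probe 1.35. Pmaip1 and Fas, under the filter and named after their values were seen, are in both the pro-apoptotic and the p53 list. Pmaip1 read 46.7 in Cre and 8.7 in Vec, under the floor, at least 4.92-fold higher. Fas read 3.0 in Cre, under the floor, and 31.2 in Vec, at least 3.28-fold lower. Genes of DNA damage response and repair had a median of 0.00 over 28 genes.

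Genes of collagens and other matrix proteins had a median of -0.46 over 35 genes, below all 10000 random lists, and 32 of the 35 ratios were negative. At least 2-fold lower were 5 of them: Col3a1, Col12a1, Lox, Col1a2 and Thbs1, the last named after its value was seen. Lox, which encodes the enzyme that crosslinks collagen, read 970.3 in Cre and 2307.5 in Vec. Col1a2 read 1710.6 and 3844.6, and Thbs1 had a log2 ratio of -1.03. Fibroblast markers had a median of -0.27 over 14 genes, with 3 at least 2-fold lower, and -0.21 over the 9 genes that are not in the matrix list. Col1a1, a fibroblast and TGF-beta target gene, was 1.87-fold lower and Postn 1.90-fold lower, while the TGF-beta target list lay inside its random range at -0.09 over 21 genes. As a sign of RNA quality, the 3' over 5' signal ratio of Gapdh was 0.827 in Cre and 0.848 in Vec, that of beta-actin 1.01 and 0.939, and that of the transferrin receptor 4.13 and 3.15.

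**Figure D3:**
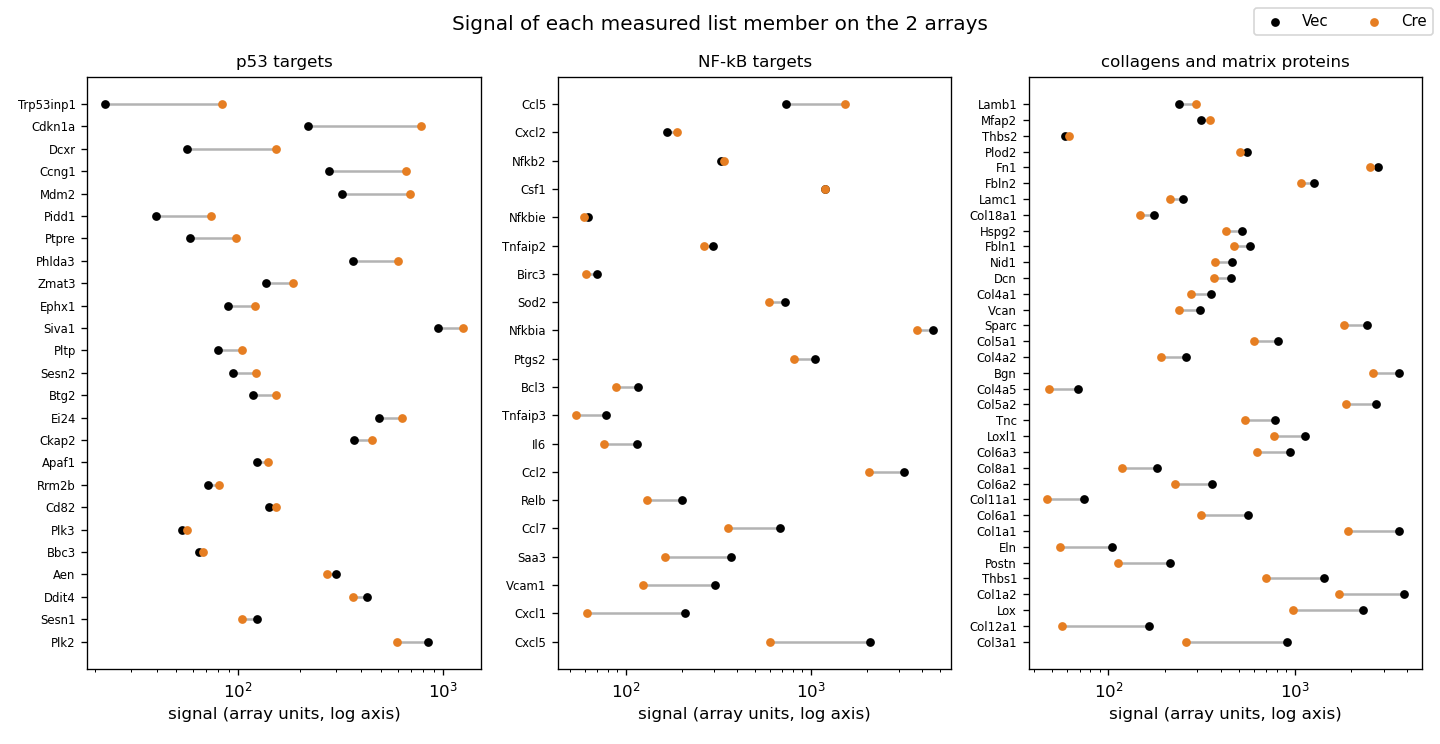
Each row is a gene of the p53 target, NF-kB target or matrix list, with its signal in the Vec library (black) and in the Cre library (orange) in array units on a log axis. The p53 targets lie mostly to the right in Cre, and 16 of 20 NF-kB targets and 32 of 35 matrix genes lie to the left.

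Actin cytoskeleton and smooth muscle genes had a median of -0.34 over 22 genes, below all random lists, with 18 negative ratios and 1 gene at 2-fold. That gene was Acta2, which encodes smooth muscle actin and read 1245.2 in Cre and 3025 in Vec. This probe is of a class that can bind several transcripts, and the other Acta2 probe, dim at 12.7 and 11.3, had a log2 ratio of 0.17. Cnn1, Fhl1 and Tpm4, of the contractile and actin-binding apparatus, were 1.997-fold, 1.93-fold and 1.70-fold lower, all under the 2-fold rule. Integrin and focal adhesion genes had a median of -0.11 over 21 genes, inside the random range. Growth factors and their receptors had a median of -0.19 over 27 genes, with 2 at least 2-fold lower, the receptor genes Pdgfrb (2.15-fold, but under 2-fold with the median over its probes) and Met (2.11-fold). Matrix proteases and inhibitors had a median of 0.10 over 14 genes, and the protease gene Adamts5 was 2.39-fold lower, while its other probe, under the filter, read 46.5 in Cre and 43.3 in Vec.

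NF-kB targets had a median of -0.39 over 20 genes, below all random lists, with 16 negative ratios. Cxcl5, Cxcl1, Vcam1 and the acute phase gene Saa3 (2.28-fold) were at least 2-fold lower. Ccl5, a T cell chemokine gene, went the other way at 1522 in Cre and 729.1 in Vec, 2.09-fold higher. The list of secreted chemokines and cytokines had a median of -0.60 over 15 genes and a mean of -0.31, with 6 positive and 9 negative ratios. Without the members it shares with the NF-kB list its median was -0.15 over 7 genes, inside the random range, and with no filter on dim probes it was 0.00. The NF-kB median over the next brightest probes of 7 genes was -0.14, also inside its random range.

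Interferon-stimulated genes had a median of 0.00 over 26 genes and did not stand apart, but 3 were at least 2-fold higher and 1 at least 2-fold lower. The antiviral genes Rsad2 (2.18-fold) and Ifit1 (2.10-fold) and the RNA sensor gene Ifih1 were higher, and Bst2, which encodes the tethering protein of virus particles, was 2.07-fold lower. With the filter at the 75th percentile of signal the list lay above its random range, at a median of 0.72 over 6 genes. That filter uses the mean of both arrays, and the 5 genes whose Vec signal alone reached it had a median of 0.15. The 9 genes of MHC class I and antigen presentation had a median of 0.17, inside the random range, and 0.08 without probe sets that may cross-hybridize. The peptide transporter genes Tap1 and Tap2 had log2 ratios of 0.65 and -0.62, the peptide loading gene Tapbp -0.38, and H2-K1, on a probe of a class that can bind several transcripts, 0.58.

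The immediate early and AP-1 list had a median of 0.11 over 30 genes, inside the random range, with 3 genes at least 2-fold higher. These were Dusp1 (2.15-fold), a phosphatase of MAP kinases, Fosl1 (2.13-fold), a partner of Jun, and the stress factor Atf3 (2.10-fold). With the median over its probes Fosl1 had a log2 ratio of 0.74, under 2-fold. Jun itself read 526.9 in Cre and 597.2 in Vec. In the unfolded protein response list, whose median of -0.10 over 27 genes lay inside the random range, Atf3, which is also in that list, was the 1 gene at 2-fold, and the next log2 ratios by size were -0.99 for Herpud1, 0.96 for Ppp1r15a and 0.93 for Ddit3. Amino acid response genes had a median of 0.05 over 26 genes, and heat shock genes -0.04 over 21 genes with Hspa1a as the 1 gene at 2-fold. The 4 measured histone genes, too few for a list value, ranged from -0.19 for H2az1 to 0.65 for H1f2.

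The list of PP2A-family phosphatase subunits, of the family that alpha4 is associated with, also holds regulators such as Set. Its median was 0.02 over 22 genes with 11 positive and 11 negative ratios. The catalytic subunit genes Ppp2ca, Ppp4c and Ppp6c had log2 ratios of 0.13, -0.07 and 0.18, and the scaffold gene Ppp2r1a 0.04. The largest was Set, which encodes an inhibitor of PP2A, at 1692.5 in Cre and 2508.5 in Vec. With the median over probes the log2 ratio of Set was -0.27 and that of Ppp6c -0.11, and those of Ppp2ca and Ppp2r1a were also below 0. Mid1, the gene of an alpha4-binding ubiquitin ligase, was under the filter at 22 in Cre and 20.4 in Vec.

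In the lists of energy and lipid metabolism, Scd2 and the hypoxia list member Lox were the genes at 2-fold, both lower in Cre. Oxidative phosphorylation genes had a median of 0.24 over 48 genes, above all random lists, with 39 positive ratios, among them Atp5e, Uqcrfs1 and Sdhd with log2 ratios of 0.83, 0.69 and 0.58. Glycolysis genes had a median of -0.17 over 15 genes at percentile 1.28, which 2 of the 8 alternatives that moved any list brought inside the random range, and hypoxia genes a median of -0.27 over 18 genes at percentile 0.01. Without the members shared with glycolysis the hypoxia median was -0.16 over 13 genes, at percentile 1.75. Hk2, which encodes a hexokinase, was 1.73-fold lower, and the glucose transporter gene Slc2a1 1.42-fold lower. Fatty acid synthesis genes had a median of -0.28 over 13 genes, led by the desaturase gene Scd2 (2.05-fold lower, the 1 gene at 2-fold) and Fads2 (1.61-fold lower). Cholesterol synthesis genes had a median of -0.24 over 18 genes, 12 of them negative, with Cyp51 at 1.72-fold lower and Lss at 1.53-fold higher.

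Proteasome subunit genes had a median of 0.20 over 30 genes at percentile 99.97, with 25 positive ratios and none at 2-fold; Psmb6 and Psmb4 had log2 ratios of 0.54 and 0.50. Nrf2 antioxidant genes had a median of 0.17 over 22 genes at percentile 97.8, just above a random range that ended at 0.16, and 4 of the 8 alternatives that moved any list brought the list inside its range. Their largest ratios were 1.82-fold for Nqo1, the gene of a quinone reductase, and 1.68-fold for Hmox1, the gene of an enzyme of heme breakdown. Lysosome and autophagy genes had a median of 0.13 over 28 genes, inside the range, with Map1lc3a at 2.04-fold. The metallothionein gene Mt1 is in a list with 4 genes past the filter, too few for a list value. It was 1.69-fold higher on a probe of a class that can bind several transcripts. Its other probe, under the filter, read 7.1 in Cre, under the floor, and 19.1 in Vec.

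Cell cycle and translation genes did not stand apart. Medians were 0.00 over 43 genes of G1/S and DNA replication, -0.04 over 46 genes of G2/M and mitosis, -0.07 over 40 cytosolic ribosomal protein genes, -0.05 over 28 translation factor and TOR pathway genes and -0.03 over 27 genes of ribosome biogenesis. The ribosomal protein median changed sign, to 0.07 with quantile normalization and 0.04 with lowess centring. Ube2c, a mitotic ubiquitin-conjugating enzyme gene, had a log2 ratio of 0.56, and Nusap1, a spindle protein gene, 0.66.

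Markers of other cell types were mostly under the filter. Of the macrophage and leukocyte markers 4 of 26 passed, with Cd14 the brightest at 217.3 in Cre and 246.3 in Vec. Endothelial markers passed for 2 of 17 genes, and the brightest, Cd34, read 69.9 and 109.9. Epithelial markers passed for 3 of 21 genes, and the keratin gene Krt8, 2.10-fold lower, was the 1 marker past the filter at 2-fold. Of the others, 2 of 12 adipocyte, 1 of 26 skeletal muscle, 3 of 21 neural, 3 of 12 chondrocyte and osteoblast and 0 of 10 erythroid markers passed. The brightest of these were Fabp5, at 1181 and 1251.6, and Nes, at 565.5 and 482.5. The other probes of Krt8, under the filter, read 5.9 in Cre and 13.3 in Vec, and 2.1 and 3.0. Markers under the filter were at 2-fold in either direction, such as Eng (4.52-fold lower) and Mbp (3.56-fold higher), named after their values were seen.

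The control probes asked how alike the 2 hybridizations were. All 18 spike-in probes, of bacterial bio genes and the phage P1 cre gene, were lower on the Cre array, with a median log2 ratio of -0.72 and a range of -1.50 to -0.44. Scaling the arrays on these probes, an alternative chosen after the data were seen, moves every log2 ratio up by 0.72 and gives 1443 genes higher and 4 lower in place of 38 and 51, so that all directions given here are relative to the median gene and not per spiked amount. The P1 cre probes were 17.3 times the bio probes on the Cre array and 16.6 times on the Vec array, a log2 difference of 0.05. No separate signal of Cre transgene RNA was therefore seen over the spiked P1 cre. The log2 ratios of the P1 cre probes ranged from -0.91 to -0.47, so this comparison could miss a weak transgene signal and does not show that Cre RNA was absent. The 18S ribosomal RNA signal over the beta-actin signal was 0.0332 in Cre and 0.012 in Vec.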

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

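Of the tests in this part, the one on dim probes and the one on dilution were set before their results were seen, lowess centring was an alternative fixed beforehand but set against these patterns only after they were seen, and the other tests, with the interval on the dim probes, were chosen after the results were seen.

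Signal of 18S ribosomal RNA, outside the gene comparison, differed between the arrays. The 3 probes of 18S ribosomal RNA were 2.575-fold (3' probe), 1.862-fold (5' probe) and 1.776-fold (middle probe) higher on the Cre array. Of 900 probes past the filter with no single gene name, 12 were at least 2-fold apart, 6 higher and 6 lower in Cre. This share is close to that of the named genes past the filter (89 of 6842, or 1.3%), so these probes do not stand out.

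The list of p53 targets was higher in the Cre library. A bias that depends on brightness is argued against by the random lists, which were matched on signal. With lowess centring the list median was 0.388, above all random lists, which adds little because that matching already allows for such a bias. Noise or cross-hybridization of single probes is argued against only for the 8 members with a next brightest probe past the filter. These probes had a median of 0.602, above the random range of -0.284 to 0.228. The 8 include Cdkn1a, Mdm2 and Ccng1. The other members, with Trp53inp1 and Dcxr among them, are not covered, so for them it stays open. Whether the shift may come from loss of the floxed gene or from Cre activity itself cannot be told apart, because 0 samples of the series combine Cre with cells lacking the floxed allele. With 1 sample per group, a difference between the cultures that does not come from Cre cannot be told apart from these either.

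The matrix list was lower in the Cre library. A bias that depends on brightness is argued against by the random lists, which were matched on signal, and a median of -0.461 with lowess centring adds little to that. Single-probe noise is argued against only for the 19 members with a next brightest probe. These probes had a median of -0.538, below the random range of -0.197 to 0.126. For the other members it stays open. Dilution by cells that lack matrix genes would lower all members by the same factor; the SD of the members' log2 ratios was 0.449 with a jackknife error of 0.068, against 0.228 to 0.441 for random lists, a margin smaller than the error, so it stays open. Degraded RNA in the Cre library also stays open, since the 3' over 5' ratio was higher in Cre by up to 0.39 on the log2 scale, for the transferrin receptor, and by 0.11 for beta-actin and -0.04 for Gapdh. A response to the loss of the floxed gene, Cre activity itself or a difference between the cultures may also account for the shift. With 1 sample per group, and 0 samples that combine Cre with cells lacking the floxed allele, these were not tested and cannot be told apart.

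Of the 4 Igbp1 probes, 1 was at least 3.43-fold lower in the Cre library and the others were apart by 1.32-fold or less. Of the 1000 probes nearest in mean signal (15.5 to 20.3), 0.5% were lower by as much, under the 1.25% set beforehand for 4 probes, but that limit did not allow for the floor, which the Cre value lies under. The means of only 831 of these probes allow so large a floored fold, and 5 of 831 is 0.602% with an exact (Clopper-Pearson) 95% interval of 0.196% to 1.40%, which holds the limit, so noise of a dim probe stays open. Whether the other probes lie outside the deleted part cannot be told apart from an incomplete deletion, because 0 of the 4 probes have an accession in the probe table and the labels do not give the deleted part.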

How the results depend on the processing

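The spike-in scaling, the rule on several probes, the lists without shared members and the next brightest probes were chosen after the data were seen. No paired analysis was possible because each group holds 1 sample. Values as deposited equal the main setting, and a floor at the 40th percentile moved no list, so neither shows anything about the stability of the lists. The 38 higher and 51 lower genes became 42 and 45 with quantile normalization (37 and 44 of them shared), 41 and 47 with lowess centring (37 and 47 shared), 34 and 46 with the median over probes and 36 and 49 without probe sets that may cross-hybridize. A pseudocount left 29 and 29, since it shrinks the ratios of dim genes. No filter gave 256 and 323, and a filter at the 75th percentile 14 and 14. A 1.5-fold threshold gave 306 and 238 and a 3-fold threshold 2 and 6. Their construction implies more or fewer genes, but not the balance. Of the genes called, 42.7% were higher in Cre at 2-fold, 56.25% at 1.5-fold and 25% at 3-fold. Scaling on the spike-in probes gave 1443 and 4, and the rule on several probes 5 and 8. Without probe sets that may cross-hybridize the Igbp1 log2 ratio was -0.003 and that of Acta2 was 0.169, each from another probe. The log2 ratio of 18S over beta-actin was 1.166 with quantile normalization instead of 1.46; the cause was not tested. Of the 14 lists that stood apart, 11 kept their side in all 8 of the other alternatives fixed beforehand; glycolysis lost it in 2, Nrf2 genes in 4 and chemokines with no filter. Unfolded protein response genes stood apart, lower, in 4, integrin genes in 2, and the interferon, TGF-beta and lysosome lists in 1 each. With the next brightest probes, the NF-kB, Nrf2, glycolysis, cholesterol, fatty acid and growth factor lists lay inside their ranges and the integrin and unfolded protein lists below. Of single gene values, 1476 stayed within the probe SD of the main value and 21 moved beyond it. The 1476 include values as deposited, and the median over probes for genes with 1 probe, which cannot move, so part of this count was fixed in advance. The sign changed in 12 values, 8 of them among these 21, of genes under 2-fold except Acta2. Signal over background limits dim genes most: the SD of log2 ratios was 0.442 over the dimmest 685 genes and 0.282 over the brightest 685.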

Other observations

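The gene families in this part, grouped by the letters that open their symbols, and the split of the interferon genes by signal were chosen after the data were seen. Genes of mitochondrial ribosomes and import were higher in the Cre library. The small mitochondrial ribosomal subunit family (Mrps) had a median log2 ratio of 0.41 over 27 genes, 25 of them positive, led by Mrps18c at 1.25 and Mrps9 at 0.90, and the large subunit family (Mrpl) had 0.25 over 47 genes, 40 of them positive. The mitochondrial import family Timm had a median of 0.26 with 12 of 13 ratios positive, and the complex I families Ndufa and Ndufb had 0.31 and 0.32, with all 12 and all 10 ratios positive. Complex I genes such as Ndufb9 are also in the oxidative phosphorylation list, so they are not separate from its shift. The 3' over 5' ratio was higher in Cre by 0.39 on the log2 scale for the transferrin receptor, 0.11 for beta-actin and -0.04 for Gapdh. Whether a difference in RNA quality bears on these mitochondrial families or on the oxidative phosphorylation list was not tested and stays open. Among the families that were lower were the zinc finger families Zbtb (-0.32 over 13 genes) and Klf (-0.28 over 10 genes, from -0.85 for Klf7 to 0.87 for Klf4) and the calpain proteases Capn (-0.28 over 8 genes). Of 94 families with at least 8 genes past the filter, 9 lay above and 8 below the central 95% of random lists. For genes drawn at random this range leaves 4.7 outside, but genes of a family can also vary together. The others above were Rnf, Ccdc, Klhl and Smim. The families given here with their medians kept their side with lowess centring and with quantile normalization. Myo and Trim, also below in the main setting, came inside their ranges with both.

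Interferon-stimulated genes were split by signal. The 6 genes with a mean signal at or above 182.8, the 75th percentile over probes, had a median log2 ratio of 0.72 with 5 positive, and the 20 dimmer genes had -0.09 with 8 positive. The mean of both arrays also carries the difference itself, and split by the Vec signal alone the 5 brighter genes had a median of 0.15 with 3 positive. By the mean, the brighter genes include Ifih1 and Ifit1, and the dimmer ones Rsad2 and Bst2, so that genes at 2-fold lie on both sides of the split. The difference between the brighter and dimmer genes was not tested.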
